A study of Mus musculus with 72 samples.

How the data were processed

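RNA of liver and gastrocnemius muscle was extracted with TRIzol and made into libraries with the TruSeq RNA v2 kit, which does not mark strand, per the labels' protocols. The libraries came from fed and 24-h fasted male C57BL/6J mice aged 8 weeks, with 3 libraries per tissue, feeding state and time, at 6 times 4 h apart. Each library was assigned to its group from the tissue, feeding state and time in its labels, and every column of the tables was matched to its library by name. Replicates are libraries that the labels number separately within a group. Labels do not say how libraries of different numbers relate, so p-values measure the spread between these separate samples.

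The authors deposited 3 tables, with values for whole genes (20561 genes), exons and introns (19433 genes each). The unit of the deposited values was taken as FPKM from the values themselves: none is below 0, they are not whole, their totals differ between libraries, and the steps between low values scale with the inverse of transcript length. Whether single reads or fragments were counted is unknown. The genome build was mm10 and the Illumina software CASAVA 1.8.2, per the submitters' processing notes; the aligner, the counting tool and the annotation are not given in the sources used here. The exonic and intronic tables are each scaled to a total of their own, so an intronic change is relative to all intronic signal of the library. Coordinates of named genes are on mm10, 1-based, from GENCODE M21, matched by symbol.

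Read depth was estimated from the low values. In the exonic table, 61% of 31423 values of 1 to 10 estimated reads lay within 0.1 of a whole read, against 20% by chance. The whole-gene table rested on an estimated median of 25.5 M reads, from 581 genes of 1 transcript of which 44.6% gave the commonest total, and the exonic table on 20.7 M (range 13.3 to 28.9). Whole reads could not be recovered for nearly all genes, so no count test was run.

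Values were analysed as log2(FPKM + 0.5) in R 4.3.3 with limma 3.58.1 (empirical Bayes with a trend). Genes with at least 1 FPKM in at least 3 libraries of the tissue were tested, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The fasting effect was fitted in the 36 libraries of a tissue with time as a 6-level factor. The tissue difference was the interaction of tissue and feeding state, averaged over the 6 times, in a model of 24 group means. Rhythms were tested in 1 fit per tissue with an intercept and a 24-h cosine and sine for each feeding state, by F tests with 2 degrees of freedom of the fed terms, the fasted terms and their difference. Amplitudes and peak times come from the same fit. A gene lost its rhythm where the difference and the fed rhythm passed and the fasted rhythm had an unadjusted p over 0.05, and gained one in the reverse case. The exonic minus intronic effect was fitted to the difference of both log2 values within each library, for genes that passed the filter in both tables. Lists were tested with camera, with an inter-gene correlation estimated for each list of at least 3 tested genes. Tables were joined and figures drawn with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

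The tests, the filter, the pseudocount, 35 gene lists and the rule for named genes were set before the data were examined. The lists cover the core clock and clock output, fatty acid oxidation and ketogenesis, gluconeogenesis and amino acid catabolism, the urea cycle, insulin and FOXO responses, fatty acid and triglyceride synthesis, cholesterol, bile acids, autophagy, glucocorticoid and CREB responses, ubiquitin ligases and the proteasome, muscle glucose use, liver glycolysis, oxidative phosphorylation, endoplasmic reticulum chaperones, heat shock, extracellular matrix, cell cycle, ribosomal proteins, xenobiotic metabolism, the somatotropic axis, and markers of 12 cell types. By the rule, the genes named were, per tissue, the 5 largest rises and 5 largest falls among genes past the threshold with the same sign at all 6 times; up to 4 members of a list with the smallest adjusted p and the member with the largest change that did not pass; all core clock genes; the 5 losses and 5 gains of rhythm with the smallest p of the difference and 3 clock output genes; the 5 largest differences between tissues in each direction among genes changed in opposite directions; and the 5 largest exonic minus intronic differences in each direction. Gene models without a symbol were counted but not named, and some genes that the rule names are not reported here. The list rule was also used for the lists described in the exonic minus intronic comparison, and Alb, Acta1, Apoa1, Ckm, Saa1 and Gapdh were added as examples of level, both after the data were seen.

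The model code was tested on simulated data with 200 changed genes. For the fasting effect in liver (10780 genes), 56.1%, 94% and 100% of true changes of 0.25, 0.5 and 1 log2 were recovered, and 56.1%, 91% and 98.5% in muscle (11223 genes). For the rhythm difference, 13.4% in liver and 25.4% in muscle were recovered at an amplitude of 0.25 log2. At 0.5 log2, 77.6% in liver and 77.6% in muscle were recovered. Replicates were compared over genes of at least 10 FPKM: across the 72 pairs within groups the SD of the log2 difference was 0.132 to 0.80, above the 0.0604 that counting alone gives for 2-kb transcripts, so no pair was treated as a repeat deposit of 1 library.

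Alternatives set beforehand were pseudocounts of 0.1 and 1, no filter, median-of-ratios scaling, quantile normalisation, robust empirical Bayes, a replicate block, no time covariate, a 6-level time factor for rhythms, a preset inter-gene correlation of 0.01 and leaving out each library in turn. Added after the data were seen were the times whose fed libraries lacked transcripts of the other tissue, ZT0 alone in liver with and without the length trend, leaving out genes at least 100 times higher in the other tissue, removing a trend with transcript length, leaving out 8 libraries of steep length slope (log2 level on log2 length, over 3 median absolute deviations from the median of their tissue and feeding state), setting intronic values per exonic read, fitting each feeding state alone, and a term for the fed times with such transcripts. An exact 0 in these tables was treated as a low value.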

Results

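Liver and gastrocnemius muscle were taken from 8-week-old male C57BL/6J mice that had either eaten freely (fed) or gone without food for 24 h (fasted). Mice were kept in a cycle of 12 h of light and 12 h of dark, and tissues were collected at Zeitgeber time (ZT) 0, 4, 8, 12, 16 and 20, where ZT0 is lights on. Polyadenylated RNA of 3 libraries per tissue, feeding state and time was sequenced, which gave 72 libraries in 24 groups, 36 per tissue and 18 per tissue and feeding state. The comparisons ask how a 24-h fast changes transcript levels in each tissue, how the response differs between the tissues, how it alters daily rhythms, and whether changes in intronic signal, a measure of unspliced RNA, accompany those in exonic signal. Estimated from the steps between low values, the whole-gene table rested on a median of 25.5 M reads per library (range 17.1 to 35.1), so that 1 FPKM on a 1-kb transcript stood for about 25.5 reads. Changes are given on the scale of log2(FPKM + 0.5), fasted minus fed, with standard errors (SE), and understate the change of genes of low level. Levels are means ± SD of 18 libraries per feeding state over the 6 times.

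Some fed libraries held transcripts of the other tissue. Alb, the serum albumin gene of hepatocytes, stood at 36.9 ± 27.6 FPKM (SD, n = 12, range 23.7 to 123) in fed muscle of ZT0 to ZT12. Its level was 0.55 ± 0.854 FPKM (n = 6) in fed muscle of ZT16 and ZT20 and 0.38 ± 0.724 FPKM (n = 12) in fasted muscle of ZT0 to ZT12. Acta1, the skeletal muscle actin gene, stood at 13.4 ± 6.35 FPKM (n = 12) in fed liver of ZT8 to ZT20 and at 0.0763 ± 0.0664 FPKM (n = 6) in fed liver of ZT0 and ZT4. The 3 fasted liver libraries of ZT4 had 126, 25.6 and 0.862 FPKM of Acta1, and fasted liver of ZT8 to ZT20 had 0.0509 ± 0.047 FPKM (n = 12). Among the genes tested, 61 in liver and 89 in muscle had a mean at least 100 times higher in the other tissue. Where such a gene is named, the ratio of its means is given, and the counts of genes changed within a tissue (whole gene, intronic, and exonic minus intronic) were also computed at the 2 times whose fed libraries lacked these transcripts (ZT0 and ZT4 in liver, ZT16 and ZT20 in muscle). Since fasted liver of ZT4 held muscle transcripts, liver was also tested at ZT0 alone.

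**Figure D1:**
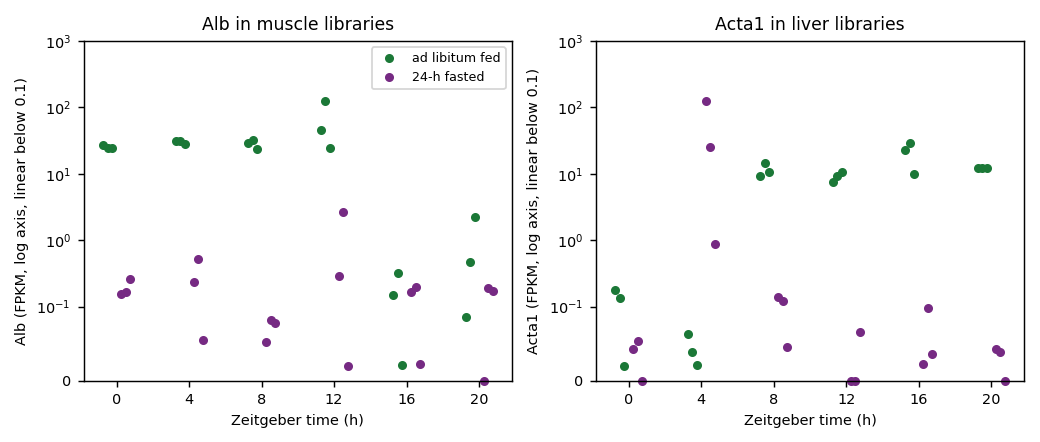
Alb in the 36 muscle libraries (left) and Acta1 in the 36 liver libraries (right) against Zeitgeber time, in FPKM on a logarithmic axis that is linear below 0.1; each point is 1 library, green for fed and purple for fasted, spread sideways for legibility. Fed muscle of ZT0 to ZT12 lies between 23.7 and 123 FPKM of Alb, and fed liver of ZT8 to ZT20 between 7.47 and 29.3 FPKM of Acta1.

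In fasted liver, most measured genes of fatty acid oxidation, ketogenesis and gluconeogenesis rose, and most of fatty acid and cholesterol synthesis fell (18 libraries per feeding state). Tested as lists with an estimated correlation, the first 2 passed (camera, adjusted p = 0.0109 and 0.00296) and the 2 synthesis lists did not (adjusted p = 0.0794 and 0.169). The largest rise was that of Cyp4a14, a fatty acid omega-hydroxylase gene and target of PPARα (chromosome 4, 115486200 to 115496142; mm10), from 15.3 ± 17.6 to 3765 ± 816 FPKM, a log2 change of 8.59 ± 0.34 (limma, adjusted p = 8.60e-21). It was followed by its paralog Cyp4a10 (6.88 ± 0.17), the metallothionein genes Mt2 (6.51 ± 0.39) and Mt1 (5.87 ± 0.36), and Cyp4a31 (5.14 ± 0.15). The largest fall was that of Hsd3b5, a male-biased steroid dehydrogenase gene (chromosome 3, 98618634 to 98630252), from 169 ± 67.2 to 3.03 ± 2.97 FPKM (-5.92 ± 0.23, adjusted p = 5.11e-21). Next came the fatty acid binding protein gene Fabp5 (-5.57 ± 0.19), the lipogenic regulator Thrsp (-5.56 ± 0.26), the carbonic anhydrase gene Car3 (-5.29 ± 0.33) and Serpina4-ps1 (-5.26 ± 0.33). By the rule for naming them, these 10 genes had the same sign of change at all 6 times. Reads of the Cyp4a, Mt, Hsd3b and Serpina families can be shared between near-identical copies, so the division of signal among paralogs is uncertain.

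Of 10780 genes tested in liver, 7865 changed (73%), 2691 up and 5174 down, and 374 rose and 764 fell at least 2-fold (limma, Benjamini-Hochberg adjusted p under 0.05). The median change of all genes was -0.13, and list medians are given relative to it. With median-of-ratios scaling, which sets that median near 0 (0.018), 4054 genes were higher and 3819 lower, that is 51.5% higher against 34.2%, and with quantile normalisation 4011 were higher and 3893 lower. The first principal component held 57.3% of the variance, and all 18 fasted libraries lay on one side of every fed library. At ZT0 and ZT4 alone (6 libraries per feeding state), 7141 genes changed, of which 6384 were among those changed over all times. At ZT0 alone (3 libraries per feeding state), 7485 genes changed, and 7361 with a trend with transcript length removed from each library. The slope of that trend, in log2 level per log2 length relative to the mean of the tissue, was -0.111, -0.0893 and -0.163 in the fed and 0.0807, 0.0961 and 0.0631 in the fasted libraries of ZT0, and their relative ratio of intronic to exonic depth 0.422 ± 0.0861 (SD, n = 3) and 1.81 ± 0.108.

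Among the lists fixed before the data were examined, fatty acid oxidation and ketogenesis rose in liver: of 28 members, 25 rose, 2 fell and 1 did not pass (median 1.30; camera, adjusted p = 0.0109 with an estimated correlation). Besides the Cyp4a genes, the acyl-CoA thioesterase gene Acot1, whose paralog Acot2 can share its reads, rose by 3.81 ± 0.16, and Acadm, the medium-chain acyl-CoA dehydrogenase gene, by 1.23 ± 0.054, whereas Hadh did not pass (-0.16 ± 0.10) but fell at ZT0 and ZT4 alone and passed without fasted ZT12 replicate 2 (0.0473), with the adjusted p in parentheses. Of 17 genes of gluconeogenesis and amino acid catabolism, 13 rose, 3 fell and 1 did not pass (median 1.52, adjusted p = 0.00296 with an estimated correlation), among them the transaminase genes Got1 (2.92 ± 0.14) and Gpt2 (1.44 ± 0.071) and the tryptophan dioxygenase gene Tdo2 (1.60 ± 0.089). Of 6 urea cycle genes, 4 rose, 1 fell and 1 did not pass (adjusted p = 0.0537 with an estimated correlation). Asl (1.90 ± 0.089), Cps1 (1.29 ± 0.069) and Arg1 (1.14 ± 0.067) were among these genes. Glucocorticoid-responsive genes gave 13 rises and 2 falls of 15 (adjusted p = 0.0537 with an estimated correlation). The chaperone gene Fkbp5 (2.78 ± 0.15) and the transcription factor gene Cebpd (2.25 ± 0.13) were among these genes. Of 18 insulin- and FOXO-responsive genes, 11 rose, 3 fell and 4 did not pass (adjusted p = 0.169 with an estimated correlation). Igfbp1 (4.76 ± 0.31), Cdkn1a (3.99 ± 0.19) and Ddit4 (3.68 ± 0.32) were among these genes. Of 12 CREB-responsive genes, 9 rose, 0 fell and 3 did not pass (adjusted p = 0.295 with an estimated correlation). The coactivator gene Ppargc1a (2.10 ± 0.15) was among these genes.

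Most genes of lipid synthesis fell. All 24 genes of cholesterol synthesis and uptake fell (median -2.65, adjusted p = 0.169 with an estimated correlation; 23 with median-of-ratios scaling). The mevalonate pathway genes Mvd (-3.86 ± 0.15) and Pmvk (-2.84 ± 0.10) were among them. Of 21 genes of fatty acid and triglyceride synthesis, 2 rose, 19 fell and 0 did not pass (median -2.70, adjusted p = 0.0794 with an estimated correlation), with the regulator Srebf1 (-4.28 ± 0.14) and the citrate lyase gene Acly (-3.44 ± 0.13). Of 14 genes of hepatic glycolysis and glycogen, 4 rose, 9 fell and 1 did not pass (adjusted p = 0.428 with an estimated correlation). The pyruvate kinase gene Pklr (-3.55 ± 0.19) was among these genes. Of the 15 members of the muscle glucose use list measured in liver, 3 rose, 9 fell and 3 did not pass (adjusted p = 0.89 with an estimated correlation). Of those that fell, Pfkm (-0.77 ± 0.077) and Pkm (-0.80 ± 0.12) had means 247 and 291 times higher in muscle.

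None of the lists of protein turnover and chaperones passed in liver with an estimated correlation, each with its adjusted p given here. Of 24 autophagy and lysosome genes, 12 rose, 8 fell and 4 did not pass (adjusted p = 0.428 with an estimated correlation), with Map1lc3b (1.02 ± 0.071) and Bnip3 (1.46 ± 0.12) among the rises and the cathepsin gene Ctsb (-0.80 ± 0.071) among the falls. At ZT0 and ZT4 alone 6 rose and 9 fell, and at ZT0 alone 9 and 7. Of 11 ubiquitin ligase and proteasome genes, 9 rose, 1 fell and 1 did not pass (adjusted p = 0.0569 with an estimated correlation). At ZT0 and ZT4 alone 4 rose and 1 fell, and at ZT0 alone 5 and 1. Fbxo31 (2.56 ± 0.13) was among these genes. Of 12 cytosolic heat shock genes, 7 rose, 0 fell and 5 did not pass (adjusted p = 0.299 with an estimated correlation). Hspa8 (0.85 ± 0.13) and Hspd1 (0.40 ± 0.053) were among these genes. Of 16 endoplasmic reticulum chaperone genes, 1 rose, 10 fell and 5 did not pass (adjusted p = 0.89 with an estimated correlation). Pdia6 (-1.39 ± 0.14) and Xbp1 (-1.06 ± 0.099) were among these genes. For oxidative phosphorylation, 1 gene rose and 11 of 23 fell on the deposited scale, against 5 and 3 with median-of-ratios scaling and 6 and 5 with quantile normalisation (adjusted p = 0.961 with an estimated correlation). At ZT0 and ZT4 alone 1 rose and 20 fell, and at ZT0 alone 1 rose and 21 fell. The length slopes parted fed from fasted liver libraries at ZT0, and also at ZT8, ZT16 and ZT20. With the length trend removed, 1 rose and 18 fell at ZT0 and 2 rose and 7 fell over all times. For bile acid synthesis and transport, 2 rose and 8 of 15 fell, against 3 and 3 with median-of-ratios scaling (adjusted p = 0.961 with an estimated correlation). At ZT0 and ZT4 alone 2 rose and 4 fell, and at ZT0 alone 4 and 5. The export pump gene Abcb11 (-1.62 ± 0.094) fell, the hydroxylase gene Cyp8b1 (1.49 ± 0.11) rose, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, did not pass (-0.42 ± 0.28). Ribosomal protein genes gave 0 rises and 17 falls of 21, against 1 and 6 with median-of-ratios scaling (adjusted p = 0.89 with an estimated correlation).

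Matrix, cell cycle and non-parenchymal marker genes fell more often than they rose in fasted liver. Of 15 extracellular matrix genes, 0 rose, 11 fell and 4 did not pass (adjusted p = 0.709 with an estimated correlation), with the collagen gene Col3a1 (-2.61 ± 0.14) among the falls. All 8 cell cycle genes fell (adjusted p = 0.428 with an estimated correlation), among them the cyclin D1 gene Ccnd1 (-2.30 ± 0.20). Beside them, 9 of 12 macrophage markers, 8 of 11 endothelial markers, 7 of 11 stellate cell and fibroblast markers and 6 of 6 cholangiocyte markers fell, and 1, 0, 3 and 0 rose. Their adjusted p with an estimated correlation were 0.89, 0.89, 0.93 and 0.428. The macrophage marker Cd5l (-1.23 ± 0.15), the endothelial marker Kdr (-0.75 ± 0.13) and the cholangiocyte marker Spp1 (-1.88 ± 0.16) were among them, whereas Pdgfra of the stellate list rose (0.73 ± 0.073). Of the hepatocyte markers themselves, 3 rose, 6 fell and 1 did not pass (adjusted p = 0.961 with an estimated correlation), with the transthyretin gene Ttr (-1.16 ± 0.092) among the falls. Skeletal muscle markers in liver gave 10 falls of 11 over all times, but 3 rises and 0 falls at ZT0 and ZT4, where fasted ZT4 libraries held muscle transcripts, and 0 rises and 2 falls at ZT0 alone, or 1 rise and 0 falls there with the length trend removed (adjusted p = 0.89 with an estimated correlation). Of the slow fibre markers in liver, 1 rose, 3 fell and 0 did not pass (adjusted p = 0.961 with an estimated correlation). The falls included Tnnc1 (-0.99 ± 0.17, mean 89 times higher in muscle) and Tnnt1 (-0.41 ± 0.13, 142 times), and neither passed at ZT0 and ZT4, though both fell at ZT0 alone (-1.07 and -0.34); Tnnt1 did not pass with quantile normalisation, nor at ZT0 with the length trend removed. Adipocyte markers gave 1 rise, that of the lipid droplet gene Cidec (4.97 ± 0.20), and 2 falls of 4 (adjusted p = 0.961 with an estimated correlation). Of the erythroid, pancreas and nerve markers 1 gene each fell, Alas2 (-1.68 ± 0.11), Cela2a (-0.71 ± 0.11) and Pmp22 (-0.45 ± 0.080), and of the 2 neutrophil markers none passed in limma, with 0 at an unadjusted p under 0.05. The hepatocyte markers gave, at ZT0 and ZT4 alone and then at ZT0 alone, 1 and 0 rises and 6 and 7 falls, and the muscle glucose use list 3 and 3 rises and 5 and 9 falls. Adjusted over the list alone, the liver lists gave the same counts, except the urea cycle (4 rose, 2 fell) and oxidative phosphorylation (1 rose, 10 fell).

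**Figure D2:**
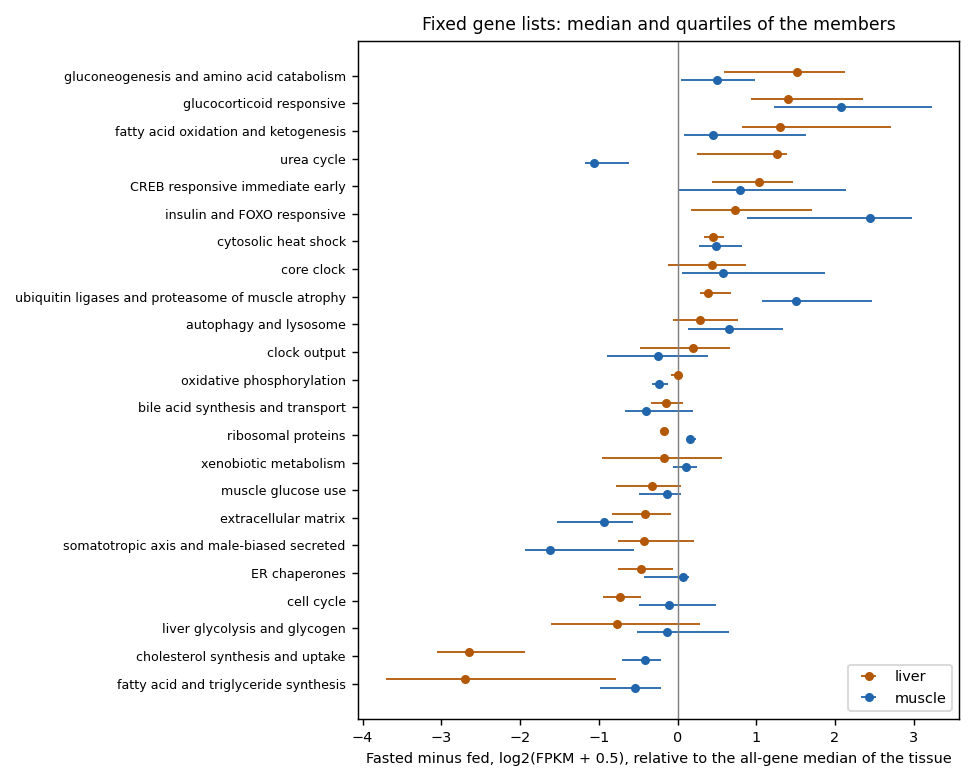
Fasted minus fed change of the 23 fixed lists that are not cell type markers, in log2(FPKM + 0.5) relative to the median of all genes of the tissue; points are the medians of the members, bars run from their lower to their upper quartile, orange for liver and blue for muscle. Cholesterol synthesis lies at -2.65 in liver and -0.41 in muscle; before the all-gene median is subtracted, the sign of the median depended on the scaling for oxidative phosphorylation in liver and for ribosomal proteins, endoplasmic reticulum chaperones, cell cycle and xenobiotic metabolism genes in muscle.

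In fasted muscle, 13 of 14 genes of ubiquitin-mediated protein breakdown, 15 of 24 of autophagy and 16 of 17 insulin- and FOXO-responsive genes rose (18 libraries per feeding state). As lists they did not pass with an estimated correlation (camera, adjusted p = 0.106, 0.196 and 0.0761). The largest rise was that of Ddit4, an inhibitor of mTORC1 signalling (chromosome 10, 59949669 to 59951834), from 6.5 ± 4.97 to 380.4 ± 68.9 FPKM, a log2 change of 6.02 ± 0.17 (limma, adjusted p = 2.78e-25). Mt2 (5.15 ± 0.21), Cebpd (5.02 ± 0.14), Trim63 (4.69 ± 0.082) and Mt1 (4.50 ± 0.20) followed, and Trim63, which encodes the muscle ubiquitin ligase MuRF1, went from 136 ± 26.7 to 3493 ± 541 FPKM. The largest fall was that of Nmrk2, a nicotinamide riboside kinase gene (chromosome 10, 81198170 to 81202051), from 50.8 ± 16.6 to 1.86 ± 0.896 FPKM (-4.46 ± 0.16, adjusted p = 8.56e-23). Ky (-4.45 ± 0.14), Lrrc38 (-3.92 ± 0.13), the transferrin receptor gene Tfrc (-3.75 ± 0.12) and Alb (-3.79 ± 0.45) came next. The mean of Alb was 3208 times higher in liver. By the rule for naming them, these 10 genes had the same sign of change at all 6 times. The change of Alb ran from -5.65 to -0.062 over the times, and it did not pass at ZT16 and ZT20 alone.

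Of 11223 genes tested in muscle, 9219 changed (82.1%), 3405 up and 5814 down, and 596 rose and 808 fell at least 2-fold. The median change of all genes was -0.17. With median-of-ratios scaling 4424 genes were higher and 4634 lower (48.8% higher against 36.9%), and with quantile normalisation 4257 were higher and 4912 lower. The first principal component held 69.1% of the variance and again parted all 18 fasted libraries from every fed library. At ZT16 and ZT20 alone (6 libraries per feeding state) 7026 genes changed, of which 6914 were among those changed over all times.

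Of 14 ubiquitin ligase and proteasome genes, 13 rose, 1 fell and 0 did not pass (median 1.51; camera, adjusted p = 0.106 with an estimated correlation), including Fbxo32, the atrogin-1 gene, from 44.6 ± 14.6 to 651 ± 119.6 FPKM (3.89 ± 0.12), and Fbxo30 (2.52 ± 0.10) and Fbxo31 (1.67 ± 0.061). Of 17 insulin- and FOXO-responsive genes, 16 rose, 1 fell and 0 did not pass (median 2.45, adjusted p = 0.0761 with an estimated correlation), with Sesn1 (4.19 ± 0.089), Gadd45a (3.26 ± 0.081) and Foxo1 (2.81 ± 0.069). Of 24 autophagy and lysosome genes, 15 rose, 5 fell and 4 did not pass (adjusted p = 0.196 with an estimated correlation). Gabarapl1 (3.54 ± 0.094), Ulk1 (2.24 ± 0.066) and Sqstm1 (1.51 ± 0.057) were among these genes. Glucocorticoid-responsive genes gave 14 rises and 1 fall of 16 (adjusted p = 0.0967 with an estimated correlation), including Fkbp5 (3.12 ± 0.13) and Hif3a (1.69 ± 0.062); the receptor gene Nr3c1 did not pass (-0.16 ± 0.087, adjusted p = 0.0918). It passed without fasted ZT0 replicate 1 (0.0374), fasted ZT4 replicate 4 (0.0424), fed ZT4 replicate 1 (0.0414) or fed ZT16 replicate 5 (0.0311), with the adjusted p in parentheses, and with the length trend removed or without the libraries of steep length slope. Of 14 CREB-responsive genes, 8 rose, 3 fell and 3 did not pass (adjusted p = 0.484 with an estimated correlation), with Btg2 (3.54 ± 0.15) and Sik1 (3.23 ± 0.20) among the rises and the orphan receptor gene Nr4a1 (-1.73 ± 0.17) among the falls. Of 13 cytosolic heat shock genes, 8 rose, 1 fell and 4 did not pass (adjusted p = 0.64 with an estimated correlation). Hspb1 (1.48 ± 0.12) and Bag3 (0.88 ± 0.066) were among these genes.

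Fuel genes changed in both directions in muscle. Of 25 fatty acid oxidation and ketogenesis genes, 15 rose, 5 fell and 5 did not pass (median 0.45, adjusted p = 0.484 with an estimated correlation). Among the rises was Pdk4, the pyruvate dehydrogenase kinase that restrains glucose oxidation, from 110.4 ± 58 to 2027 ± 340.1 FPKM (4.36 ± 0.14), together with Acot2 (4.10 ± 0.088) and Ucp3 (2.33 ± 0.094). Of 16 muscle glucose use genes, 3 rose, 11 fell and 2 did not pass (adjusted p = 0.92 with an estimated correlation). The glycolytic genes Pgam2 (-2.15 ± 0.13), Hk2 (-1.26 ± 0.10) and Ldha (-0.64 ± 0.055) were among the falls, and with median-of-ratios scaling 3 rose and 7 fell. All 23 oxidative phosphorylation genes fell, with Cyc1 (-0.68 ± 0.066) and Ndufs1 (-0.44 ± 0.050) the first of them by p, against 17 falls with median-of-ratios scaling (median -0.24, adjusted p = 0.874 with an estimated correlation). Of 20 fatty acid and triglyceride synthesis genes, 2 rose, 16 fell and 2 did not pass (adjusted p = 0.874 with an estimated correlation). The rises were those of the phosphatidate phosphatase gene Lpin1 (1.70 ± 0.065) and the acetyl-CoA carboxylase gene Acacb (1.00 ± 0.057), and Mlxipl (-1.51 ± 0.079) and Srebf1 (-1.48 ± 0.062) were among the falls. Beside them, 6 of 8 adipocyte markers fell and 1 rose (adjusted p = 0.92 with an estimated correlation). The leptin gene Lep (-1.43 ± 0.21) and the perilipin gene Plin1 (-1.67 ± 0.28) were among these genes. Of 22 cholesterol genes, 2 rose, 18 fell and 2 did not pass (median -0.41, adjusted p = 0.658 with an estimated correlation). The squalene synthase gene Fdft1 (1.03 ± 0.052) was among the rises, and Dhcr7 (-1.64 ± 0.073) was among the falls. Of 10 gluconeogenesis and amino acid catabolism genes, 5 rose, 2 fell and 3 did not pass (adjusted p = 0.196 with an estimated correlation). The glutamine synthetase gene Glul (3.34 ± 0.14) was among these genes. Genes of hepatic glycolysis and glycogen gave 3 rises and 5 falls of 8 (adjusted p = 0.92 with an estimated correlation), with Pfkfb3 (1.66 ± 0.19) among the rises. Of the falls, Pygl (-1.05 ± 0.13) had a mean 107 times higher in liver.

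Of 17 extracellular matrix genes in muscle, 1 rose, 14 fell and 2 did not pass (median -0.93, adjusted p = 0.818 with an estimated correlation). The collagen genes Col6a2 (-2.35 ± 0.13) and Col5a1 (-1.70 ± 0.11) were among the falls, and the rise was that of the lysyl oxidase gene Lox (2.18 ± 0.13). Beside them, 7 of 10 fibroblast markers, 7 of 10 endothelial markers and 6 of 8 macrophage markers fell, and 1, 2 and 1 rose (each adjusted p = 0.92 with an estimated correlation). The fibroblast marker Dcn did not pass (0.089 ± 0.064) but rose with median-of-ratios scaling, while Kdr (-1.50 ± 0.12) fell. Endoplasmic reticulum chaperones gave 3 rises and 8 falls of 16, against 6 and 6 with median-of-ratios scaling (adjusted p = 0.946 with an estimated correlation), with Dnajb9 (1.85 ± 0.089) and Pdia4 (-1.13 ± 0.076) the first by p. Ribosomal protein genes gave 2 rises and 1 fall of 22, against 11 and 0 with median-of-ratios scaling and 7 and 1 with the length trend removed (adjusted p = 0.92 with an estimated correlation). Of the skeletal muscle markers, 2 rose, 8 fell and 2 did not pass on the deposited scale, against 3 rises and 4 falls with median-of-ratios scaling (median -0.051, adjusted p = 0.92 with an estimated correlation). The fast-fibre genes Mylpf (-0.71 ± 0.066) and Pvalb (-0.63 ± 0.070) were among the falls. Myh1 did not pass (0.11 ± 0.11) but rose with median-of-ratios scaling. Of the slow fibre markers, 0 rose, 3 fell and 7 did not pass, against 1 rise and 1 fall with median-of-ratios scaling (adjusted p = 0.946 with an estimated correlation). Liver transcripts moved with the fed libraries of ZT0 to ZT12: 9 of 10 hepatocyte markers fell over all times and 1 at ZT16 and ZT20 alone (adjusted p = 0.818 with an estimated correlation). Of the urea cycle genes, 0 rose, 3 fell and 0 did not pass (adjusted p = 0.484 with an estimated correlation), namely Arg1, Asl and Slc25a15, with means 2049.7, 284 and 42.4 times higher in liver. Of the bile acid genes, 1 rose, 3 fell and 0 did not pass (adjusted p = 0.92 with an estimated correlation). The rise was that of Cyp27a1 (1.47 ± 0.055), and the falls included Slc27a5 (-1.29 ± 0.16) and Cyp8b1 (-0.69 ± 0.13), with means 671 and 1033 times higher in liver. At ZT16 and ZT20 alone, Alb, Arg1 and Slc27a5 did not pass, and Cyp8b1 rose (0.25). At these 2 times 1 slow fibre marker fell, 0 skeletal muscle markers rose and 6 fell, and 5 heat shock and 0 ribosomal protein genes rose. Of the other lists, 1 fatty acid oxidation, 0 gluconeogenesis and 3 hepatic glycolysis genes fell there, 1 muscle glucose use gene rose, and 2 bile acid genes rose and 1 fell. Adjusted over the list alone, the muscle lists gave the same counts, except that the neutrophil marker S100a8 also passed.

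Fasting changed many genes differently in the 2 tissues. Inmt, an indolethylamine methyltransferase gene (chromosome 6, 55170626 to 55175043), had the largest difference in favour of muscle among genes that changed in opposite directions, with changes of -4.08 ± 0.27 in liver and 2.47 ± 0.12 in muscle, a difference of 6.55 ± 0.27 (limma interaction, adjusted p = 8.58e-28). The stress-response gene Gadd45a differed by 5.12 ± 0.18, with changes of -1.87 ± 0.19 in liver and 3.26 ± 0.081 in muscle. Arrdc3 differed by 4.93 ± 0.21, the prolyl hydroxylase gene Egln3 by 4.09 ± 0.17, and Insig1, a regulator of sterol synthesis, by 3.95 ± 0.16. In the other direction, the water channel gene Aqp4 (chromosome 18, 15389496 to 15410982) changed by 1.08 ± 0.10 in liver and -3.34 ± 0.10 in muscle, a difference of -4.42 ± 0.13 (adjusted p = 4.13e-34). The lipolysis inhibitor gene G0s2 differed by -3.70 ± 0.38, the nicotinamide methyltransferase gene Nnmt by -3.60 ± 0.27, the transporter gene Slc41a3 by -3.28 ± 0.22 and Insig2, the paralog of Insig1, by -3.17 ± 0.13, with changes of 2.51 ± 0.14 in liver and -0.65 ± 0.034 in muscle. The mean of Nnmt was 105 times higher in liver than in muscle.

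Of 9419 genes tested in both tissues, 6620 differed in their response (limma, adjusted p under 0.05), 3628 with the more positive change in muscle and 2992 in liver. The larger part turned with quantile normalisation, where 3324 of 6770 were more positive in muscle, and without the filter, where 5386 of 11105 were. Among the 5688 genes that changed in both, 1333 rose in both (760.4 for independent lists), 3020 fell in both (2194 for independent lists), 682 rose in muscle and fell in liver, and 653 did the reverse. Across genes, which are not independent replicates, the changes in the tissues correlated with Pearson r = 0.422 and Spearman rho = 0.451.

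In liver, fasting changed the daily rhythm of several core clock transcripts, with smaller fitted amplitudes in the fasted state. Per1, a light- and hormone-responsive repressor of the clock (chromosome 11, 69095217 to 69109960), had a fitted amplitude (the distance from the mean to the peak in log2) of 1.57 in fed and 0.13 in fasted liver, with an SE of 0.14 (limma, difference adjusted p = 5.27e-05; 18 libraries per feeding state). It peaked at ZT 12.8 ± 0.344 h in fed liver, and its fasted rhythm did not pass (fitted peak 8.16 ± 4.14 h). Arntl, which encodes the activator BMAL1, had amplitudes of 2.13 in fed and 1.27 in fasted liver (19.2- and 5.8-fold from trough to peak), with peaks at ZT 22.1 ± 0.242 h and 21.8 ± 0.407 h (difference adjusted p = 0.00357). The repressor Nr1d1 had amplitudes of 2.59 in fed and 1.63 in fasted liver (limma, difference adjusted p = 0.010), and Nr1d2 of 2.01 in fed and 0.59 in fasted liver. Per2 had amplitudes of 1.39 in fed and 0.76 in fasted, and Per3 of 1.88 in fed and 1.11 in fasted liver, and both differences passed, as did that of Rora (0.63 in fed and 0.39 in fasted). The difference test takes amplitude and peak time together, so a pass does not show a change of amplitude alone. For Clock, Npas2, Cry1 and Cry2 the difference did not pass: amplitudes were 0.26 in fed and 0.48 in fasted, 1.38 in fed and 1.02 in fasted, 1.39 in fed and 1.26 in fasted, and 0.40 in fed and 0.29 in fasted liver. Cry1 peaked at ZT 19 ± 0.272 h and 18.6 ± 0.30 h and Npas2 at 23.7 ± 0.324 h and 23.7 ± 0.437 h. The peaks of Per2 lay at 14.1 ± 0.343 h and 13.4 ± 0.628 h and those of Per3 at 12.1 ± 0.256 h and 11.5 ± 0.432 h. Nr1d1 peaked at 7.18 ± 0.264 h and 6.62 ± 0.42 h and Nr1d2 at 10.1 ± 0.306 h and 11.2 ± 1.04 h. Cry2 peaked at 13.2 ± 0.678 h and 12.9 ± 0.929 h. The fitted peaks of Clock, whose fed rhythm did not pass, were 18.1 ± 2.12 h and 21.5 ± 1.13 h, and those of Rora, whose fasted rhythm did not pass, 13.2 ± 0.819 h and 20.0 ± 1.31 h. In mean level, 6 of 12 core clock genes rose and 3 fell with fasting (adjusted p = 0.428 with an estimated correlation), including Per1 (1.87 ± 0.22) and Clock (0.98 ± 0.12) and, falling, Per2 (-0.78 ± 0.14), which did not pass at ZT0 and ZT4 but fell at ZT0 alone (-0.53). Of the clock output genes, 6 rose, 5 fell and 3 did not pass (adjusted p = 0.89 with an estimated correlation). In libraries of ZT0 and ZT4 alone, 5 core clock genes rose and 0 fell, and 7 clock output genes rose and 2 fell. From trough to peak of the fitted FPKM + 0.5, the output genes Nampt, Ciart and Wee1 ranged 5.1-, 24.2- and 5.31-fold in fed liver. In fasted liver they ranged 1.44-, 3.05- and 1.59-fold, and all 3 differences passed. Some calls in fasted liver rested on 1 library, given here with the adjusted p without it in parentheses. The rhythm of Wee1 (adjusted p = 0.0343) did not pass without fasted ZT0 replicate 4 (0.0564), fasted ZT0 replicate 5 (0.104), fasted ZT8 replicate 2 (0.0507), fasted ZT12 replicate 2 (0.123), fasted ZT16 replicate 3 (0.0508) or fasted ZT20 replicate 5 (0.0519). That of Clock (adjusted p = 0.0292) did not pass without fasted ZT12 replicate 2 (0.0552) or fasted ZT12 replicate 5 (0.0589). Neither passed without a filter. Neither these nor the fasted rhythm of Ciart passed without the libraries of steep length slope, which takes replicates 2 and 5 from fasted ZT12. That of Rora (adjusted p = 0.0656) passed without fasted ZT12 replicate 4 (0.0469), fed ZT0 replicate 5 (0.035) or fed ZT20 replicate 1 (0.0422), and that of Nampt (adjusted p = 0.131) without fasted ZT20 replicate 5 (0.0419).

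**Figure D3:**
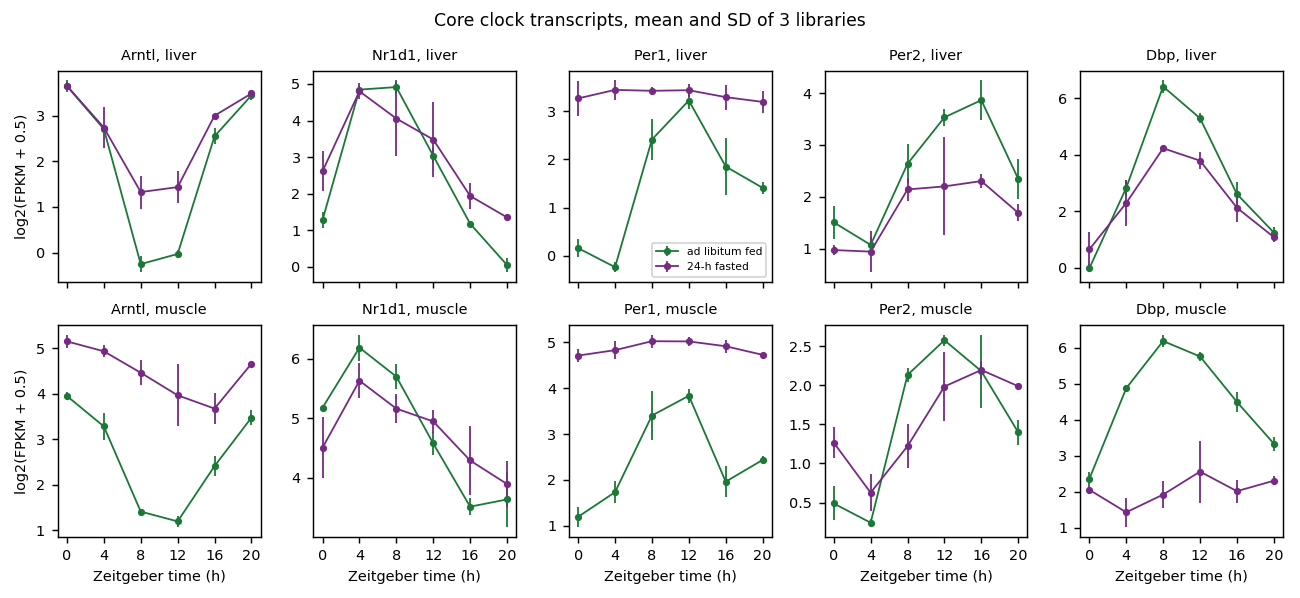
Levels of Arntl, Nr1d1, Per1, Per2 and Dbp in log2(FPKM + 0.5) against Zeitgeber time in liver (top) and muscle (bottom); points are means of 3 libraries and bars SD, green for fed and purple for fasted. The fed profile of Per1 has an amplitude of 1.57 in liver and 1.10 in muscle, and the fasted one of 0.13 and 0.18.

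Across all genes, 4278 of 10780 (39.7%) were rhythmic in fed liver and 3340 (31%) in fasted liver (limma F test of a 24-h cosine, adjusted p under 0.05), 1397 in both against 1325 for independent lists. Rhythms of an amplitude of at least 0.5 numbered 836 in fed and 390 in fasted liver. The rhythm differed between the states for 3494 genes: 1312 of them were rhythmic in fed liver with an unadjusted p over 0.05 in fasted liver (lost), and 832 the reverse (gained). With a term for the fed times that held muscle transcripts, the difference still passed for 364 of these losses and 319 of these gains. Besides Per1 and Nampt, the losses with the smallest p of the difference were Pvalb, Myh4 and Mybpc2, muscle transcripts with means 2804, 3417 and 683 times higher in muscle, whose amplitudes in fed liver were 2.35, 2.36 and 2.23. Among the gains were Rnd2 (0.16 in fed and 0.79 in fasted liver), Pfdn1 (0.13 in fed and 0.36 in fasted), the triosephosphate isomerase gene Tpi1 (0.12 in fed and 0.39 in fasted) and the cystathionine lyase gene Cth (0.14 in fed and 0.62 in fasted). With a term for the fed times that held muscle transcripts, which span 4 of the 6 times and overlap with time of day, 1741 genes were rhythmic in fed liver and 1398 differed, and Cry2, Rora, Pvalb, Myh4 and Mybpc2 no longer passed in fed liver.

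In muscle, fasting changed the rhythm of several core clock transcripts, with smaller fitted amplitudes and later fitted peaks of Arntl, Per2, Per3, Nr1d1 and Nr1d2. Arntl had amplitudes of 1.45 in fed and 0.71 in fasted muscle, with an SE of 0.093, and peaked at ZT 23.1 ± 0.245 h and 1.71 ± 0.502 h (limma, difference adjusted p = 1.98e-06; 18 libraries per feeding state). Per2 peaked at ZT 13.1 ± 0.304 h in fed and 16.1 ± 0.471 h in fasted muscle, and Per3 at 11.2 ± 0.351 h and 15.1 ± 0.399 h. Nr1d1 peaked at 5.17 ± 0.291 h and 6.68 ± 0.534 h, and Nr1d2 at 9.86 ± 0.363 h and 14.8 ± 0.597 h. The difference, which takes amplitude and peak time together, passed for all 4, with amplitudes of 1.19 in fed and 0.77 in fasted, 1.01 in fed and 0.88 in fasted, 1.40 in fed and 0.76 in fasted, and 0.54 in fed and 0.33 in fasted muscle. The amplitudes of Per3 lay close together for their SE of 0.093. Per1 had amplitudes of 1.10 in fed and 0.18 in fasted muscle (difference adjusted p = 0.00142), with a fed peak at ZT 11.3 ± 0.482 h, and its fasted rhythm did not pass (fitted peak 10.7 ± 2.99 h). Cry2 went the other way, with amplitudes of 0.40 in fed and 0.78 in fasted muscle, and its difference passed, with peaks at ZT 11.8 ± 0.808 h and 10.1 ± 0.415 h. For Clock, Npas2, Cry1 and Rora the difference did not pass, with amplitudes of 0.50 in fed and 0.33 in fasted, 0.74 in fed and 0.67 in fasted, 0.44 in fed and 0.35 in fasted, and 0.13 in fed and 0.044 in fasted muscle. Rora was rhythmic in neither state, with fitted peaks at 11 ± 3.0 h and 21.5 ± 8.95 h. The fasted rhythm of Dbp (adjusted p = 0.115) passed without fasted ZT16 replicate 2 (0.0415), with the adjusted p in parentheses. Clock peaked at ZT 0.648 ± 0.584 h and 2.93 ± 0.876 h, Npas2 at 0.62 ± 0.409 h and 2.43 ± 0.452 h and Cry1 at 20.8 ± 0.525 h and 19.7 ± 0.653 h. Among clock output genes, Dbp (chromosome 7, 45705088 to 45710203) had amplitudes of 1.81 in fed and 0.35 in fasted muscle (difference adjusted p = 1.32e-07), Ciart of 1.64 in fed and 0.89 in fasted muscle. The deubiquitinase gene Usp2 peaked at ZT 11.5 ± 0.376 h in fed and 20.9 ± 0.478 h in fasted muscle. Of the core clock genes, 7 rose, 3 fell and 2 did not pass in mean level (adjusted p = 0.106 with an estimated correlation). Cry2 (2.67 ± 0.10) and Per1 (2.45 ± 0.16) were among these genes. Of the clock output genes in muscle, 3 rose, 8 fell and 3 did not pass (adjusted p = 0.92 with an estimated correlation). Bhlhe41 (-2.84 ± 0.11) and Bhlhe40 (-2.44 ± 0.13) were among these genes.

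Rhythmic genes numbered 500 of 11223 (4.46%) in fed and 5317 (47.4%) in fasted muscle, 270 in both against 237 for independent lists, and those of an amplitude of at least 0.5 numbered 133 and 584. The rhythm differed for 3662 genes, with 123 lost and 2876 gained. With a term for the fed times that held liver transcripts, the difference still passed for 55 of these losses and 2196 of these gains. The gains were led by Zfand2a, a zinc finger gene induced by proteotoxic stress (chromosome 5, 139471211 to 139484549), with amplitudes of 0.033 in fed and 1.31 in fasted muscle and a fasted peak at ZT 9.71 ± 0.234 h (difference adjusted p = 2.42e-09). It was followed by the proton pump gene Atp6v1h (0.033 in fed and 0.96 in fasted), the ribosome export gene Nmd3 (0.10 in fed and 0.74 in fasted), Impact (0.11 in fed and 1.14 in fasted) and the selenophosphate synthetase gene Sephs2 (0.038 in fed and 0.97 in fasted). Besides Dbp, the losses with the smallest p were the liver transcripts Cpn1, Fgg, Ugt2b1 and Serpina1b, with means 353, 426, 445 and 538 times higher in liver and amplitudes in fed muscle of 0.78, 2.69, 1.18 and 2.75. In all, 41 of the 123 losses were such transcripts. In fasted muscle, 1627 of the rhythmic genes peaked from ZT8 to ZT12 (30.6%), 1264 from ZT12 to ZT16 and 1316 from ZT20 to ZT24. With a term for the fed times that held liver transcripts, 267 genes were rhythmic in fed muscle, and Cpn1, Fgg, Ugt2b1 and Serpina1b no longer passed there. In both tissues, 187 genes were rhythmic when fed (146 for independent lists) and 1323 when fasted (1424), of 9419 tested in both.

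**Figure D4:**
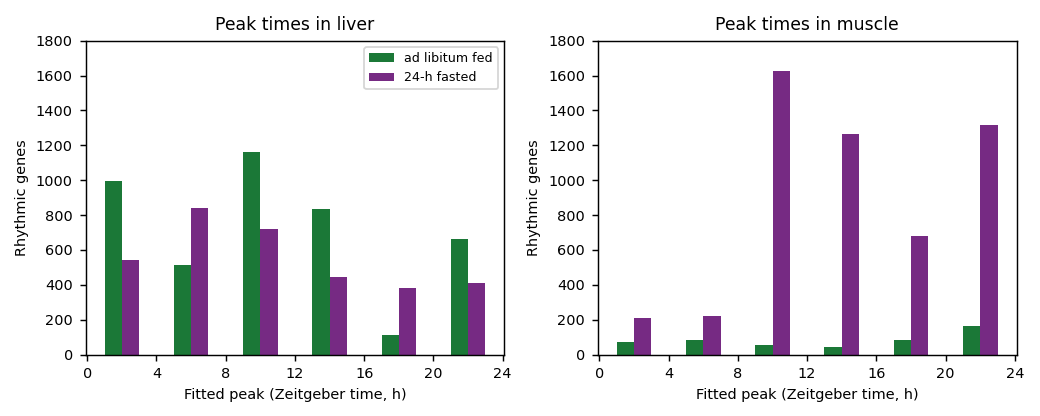
Number of rhythmic genes against the fitted peak in bins of 4 h of Zeitgeber time, in liver (left) and muscle (right), green for fed and purple for fasted, side by side within each bin. In muscle the fasted bars reach 1627 genes in the bin from ZT8, and the fed bars at most 166, in the bin from ZT20.

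In liver, intronic signal of fatty acid oxidation and cholesterol genes changed with fasting. Of 26 fatty acid oxidation genes with measured introns, 22 rose, 2 fell and 2 did not pass in intronic signal (camera, adjusted p = 0.0167 with an estimated correlation). Of 24 cholesterol genes, 0 rose, 23 fell and 1 did not pass (adjusted p = 0.0483 with an estimated correlation). Scaled per exonic read, 23 rose in the first and 20 fell in the second, among genes with both signals. The exonic change exceeded the intronic one most for the lipid droplet gene Cidec (chromosome 6, 113424634 to 113435760), whose exonic signal rose by 5.09 ± 0.20 and intronic signal by 1.48 ± 0.21, a difference of 3.61 ± 0.15 (limma, adjusted p = 9.74e-19, 18 libraries per feeding state). Ces3a (2.64 ± 0.33), Mup21 (2.41 ± 0.31), Nrp1 (2.38 ± 0.20) and Mup20 (2.31 ± 0.21) followed, and the carboxylesterase and Mup genes have near-identical copies. The difference was most negative for the transcription factor gene Klf13 (chromosome 7, 63886351 to 63938915), exonic -0.63 ± 0.12 and intronic 3.36 ± 0.14, and for Sra1 (-3.12 ± 0.21), Tmem50a (-2.81 ± 0.14), Mybpc2 (-2.75 ± 0.40, mean 683 times higher in muscle) and Hsd3b5 (-2.37 ± 0.26). Mybpc2 had a difference of 0.27 at ZT0 and ZT4, where fasted ZT4 libraries held muscle transcripts, and of -0.17 at ZT0 alone, and passed at neither. Hsd3b5 did not pass with a pseudocount of 0.1. The kit does not mark strand, so intronic reads can stem from overlapping or antisense genes.

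Of 8831 genes tested in liver, intronic signal changed for 5271, 1640 up and 3631 down (limma, adjusted p under 0.05; all-gene median -0.17), against 2496 up and 2512 down with median-of-ratios scaling. The exonic and intronic changes differed for 3128 of 8070 genes, 1930 with the exonic change the more positive (61.7%, and 52.1% with quantile normalisation). Each table is scaled to its own total: with intronic values set per exonic read, 3898 of 4776 changed genes rose in intronic signal, and the difference passed for 5095 genes with the exonic change the more positive for 154. Among 4008 genes changed in both signals, 94.9% moved in the same direction. Across genes, which are not independent replicates, the changes correlated with r = 0.856 in the same libraries and 0.807 and 0.814 between disjoint libraries. Random splits of the libraries gave a median r of 0.553 and a covariance of 0.0155 against 0.474.

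In muscle, intronic signal fell more than exonic signal for most skeletal muscle markers and glucose use genes. The largest difference was that of Mybpc2, the fast-type myosin binding protein C gene (chromosome 7, 44501699 to 44524656), whose exonic signal changed by 0.057 ± 0.045 and intronic signal by -5.18 ± 0.10, a difference of 5.23 ± 0.098 (limma, adjusted p = 1.25e-29, 18 libraries per feeding state). Myoz1 (4.74 ± 0.20), the myosin light chain gene Mylpf (4.46 ± 0.13), the fast myosin heavy chain gene Myh4 (4.41 ± 0.11) and the muscle enolase gene Eno3 (4.24 ± 0.14) followed. Of 12 skeletal muscle markers, the exonic change was the more positive for 10 and the more negative for 0 (median difference 2.41, with medians of -0.25 exonic and -2.44 intronic). In intronic signal, 11 fell (adjusted p = 0.206 with an estimated correlation). The creatine kinase gene Ckm (3.05 ± 0.098) was among them, and Tnnt3 did not pass (0.086 ± 0.10) but passed with quantile normalisation. Of 16 glucose use genes, the exonic change was the more positive for 13 and the more negative for 2 (median difference 0.90), among them Ldha (2.82 ± 0.091), Aldoa (1.97 ± 0.11) and Pfkm (2.98 ± 0.19). In intronic signal, 14 glucose use genes fell (adjusted p = 0.231 with an estimated correlation). The difference was most negative for the liver transcripts Serpina1e (-3.01 ± 0.35), Apoa1 (-2.75 ± 0.37) and Fgg (-2.46 ± 0.33), with means 690.1, 3974 and 426 times higher in liver, and for the ribosomal protein-like gene Rpl22l1 (-2.57 ± 0.099) and the integrin gene Itgb6 (-2.52 ± 0.10); Serpina1e, Apoa1 and Fgg did not pass at ZT16 and ZT20 alone.

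The FOXO-responsive, autophagy, ubiquitin ligase and glucocorticoid lists passed with a rise in intronic signal in muscle, the last with an adjusted p of 0.0453 with an estimated correlation. Of the FOXO-responsive genes 12 rose, 0 fell and 1 did not pass (adjusted p = 3.70e-04 with an estimated correlation). Of the autophagy genes, 17 rose, 1 fell and 5 did not pass (adjusted p = 3.70e-04, and 11 rises at ZT16 and ZT20 alone), and of the ubiquitin ligase and proteasome genes 11 rose, 0 fell and 2 did not pass (adjusted p = 8.46e-04). Of 9155 genes tested, intronic signal changed for 6377, 2451 up and 3926 down, against 3210 up and 3077 down with quantile normalisation. The exonic and intronic changes differed for 4375 of 8326 genes, 2238 with the exonic change the more positive, against 1332 of 4008 with intronic values set per exonic read. At ZT16 and ZT20 alone, intronic signal changed for 4154 genes and the difference passed for 2071. Among 5189 genes changed in both signals, 92.7% moved in the same direction. Across genes, the changes correlated with r = 0.81 in the same libraries and 0.791 and 0.798 between disjoint libraries. The median r of random splits was 0.592, with a covariance of 0.018 against 0.544.

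**Figure D5:**
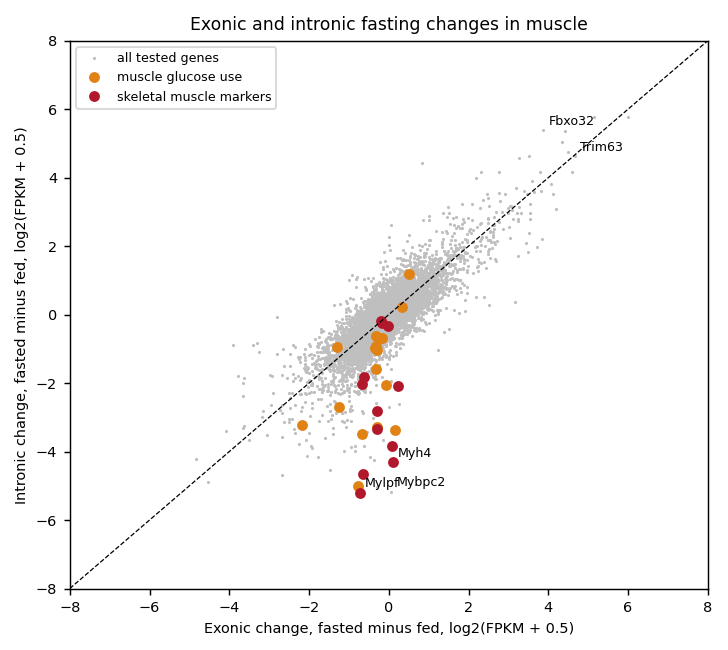
Intronic against exonic change in muscle, fasted minus fed in log2(FPKM + 0.5), for all 8326 tested genes (grey), glucose use genes (orange) and skeletal muscle markers (red), with the line of equal change dashed. Mybpc2, Mylpf and Myh4 lie below the line, at intronic changes of -5.18, -5.19 and -4.31.

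In whole-gene signal, set against all other genes with an inter-gene correlation estimated for each list (camera, adjusted over the lists of a tissue), 2 lists passed in liver, fatty acid oxidation and ketogenesis and gluconeogenesis and amino acid catabolism, and 0 in muscle, where 7 had an unadjusted p under 0.05. In intronic signal of liver the fatty acid oxidation and cholesterol lists passed, as did gluconeogenesis and amino acid catabolism (11 rose, 2 fell and 3 did not pass, adjusted p = 0.0304 with an estimated correlation), ubiquitin ligases and proteasome (5 rose, 0 fell and 3 did not pass, adjusted p = 0.0304, but 1 rise at ZT0 and ZT4 alone), FOXO-responsive genes (11 rose, 2 fell and 2 did not pass, adjusted p = 0.0483) and glucocorticoid-responsive genes (9 rose, 1 fell and 1 did not pass, adjusted p = 0.0483). With a preset correlation of 0.01, in whole-gene signal, 12 lists passed in liver and 11 in muscle.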

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

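The tests of the slope across transcripts of the other tissue, of feeding state, of the scaling of the intronic table and of a general loss of unspliced RNA were chosen only after the result was seen.

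By tests of the difference, the fasting effect differed between the tissues for 6620 genes, and the rhythm between feeding states for 3494 in liver and 3662 in muscle. Named genes with opposite changes had muscle minus liver differences of 6.55 (Inmt), 5.12 (Gadd45a), 4.93 (Arrdc3), 4.09 (Egln3), 3.95 (Insig1), -4.42 (Aqp4), -3.70 (G0s2), -3.60 (Nnmt), -3.28 (Slc41a3) and -3.17 (Insig2).

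Chance could be excluded for the counts of changed genes, since 1 of 100 splits, the real one, gave as many in each case but one: the real count and the highest of the other splits were 7865 against 6184 for fasting in liver and 9219 against 4978 in muscle, 5271 against 3201 and 6377 against 1232 for intronic signal, 3128 against 1697 and 4375 against 111 for exonic minus intronic, 4278 against 799 and 3340 against 900 for rhythms in fed and fasted liver, 500 against 134 and 5317 against 1748 in fed and fasted muscle, 3494 against 2884 for the rhythm difference in liver and 6620 against 3035 for the tissue difference. The exception was the rhythm difference in muscle, where 4 of 100 splits gave as many, 3662 against 5779. For rhythms within a feeding state, the splits exclude only equal levels at all times. Batches, such as that of the fed libraries, could beat them too. For the rhythm differences, exchanging feeding labels within a time can leave unequal mixes of fed and fasted across times. The fasting effect can then enter the time course, so these splits leave chance undecided in both tissues. What sets the splits with more genes was not tested. For the tissue difference, splits that exchanged tissue labels were tried first and replaced, after their result was seen, by the planned exchange of feeding labels, which left chance excluded as before.

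Transcripts of the other tissue appeared in fed libraries of 4 of the 6 times in each tissue. Feeding state alone is argued against, because the hepatocyte marker level of fed muscle at ZT16 and ZT20 was 2.29% of that at ZT0 to ZT12. If liver was carried over from the same mouse into fed muscle, fed liver of the same time should match best. It did so at 1 of 4 times, but the margins were narrow. Over 46 genes, r at the own time was 0.646, 0.627 and 0.752 at ZT4, ZT8 and ZT12, against a best of 0.677, 0.676 and 0.775. The match therefore decides little. The slope of the excess on the level at each time was 0.239 (95% bootstrap interval -0.165 to 0.457, 13 genes). Carry-over predicts 1, so the slope argues against it for these genes. This slope was computed after the result was seen, and another centring, tried first, also excluded 1. Across transcripts with an excess in fed muscle, the excess rose with the liver level with a slope of 1.07. These were 221 of 235, those above fed ZT16 and ZT20, with a median of 0.0873% of the liver level. In liver the slope was 0.967. Any admixture of tissue, RNA or reads gives a slope near 1, so how these transcripts came into these libraries stays open. So does muscle carried over into fed liver, as 0 muscle transcripts had the rhythm and level that the slope over times needs in at least 10. No biological explanation was tested beyond feeding state.

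More genes were rhythmic in fasted than in fed muscle. A length trend between libraries is argued against, because the ratio of fasted to fed counts was 9.4 with the trend removed, and so is a spread shared between the feeding states, with a ratio of 8.68 when each was fitted alone. A time-dependent extent of the fasting response stays open as the biological explanation: 18 of 100 orders of the fasted times explained as large a share of the fasted time course by the fasting change, the real one 23% and the highest other 40.7%, but reordering the times keeps any differences in extent between mice, so the bound set beforehand excludes nothing. At its best phase, a peak at ZT 9.97, the fasted time course followed the fasting change with r = 0.555 across genes, which are not independent replicates. The phase was chosen to fit best and no r was taken for the reordered times, so this r does not decide the question. Differences between mice killed at each time stay open, untested.

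Intronic signal of 11 of 12 skeletal muscle markers fell in fasted muscle, with a more positive exonic change for 10. Intronic signal of 7 of 10 slow fibre markers and 20 of 23 oxidative phosphorylation genes fell too, with median exonic minus intronic changes of 0.49 and 0.22, but neither list passed (adjusted p = 0.756 and 0.402 with an estimated correlation), and at ZT16 and ZT20 alone 3 and 15 fell. Scaling of the intronic table is argued against, since the skeletal muscle list's median exonic minus intronic change was 2.26 with intronic values per exonic read, as is the batch of fed libraries with liver transcripts, since it was 2.04 at ZT16 and ZT20. A general loss of unspliced RNA is argued against because the all-gene median had the opposite sign, at -4.61% of the list median. A fall in transcription of long-lived messages may be a biological explanation, as an untested hypothesis, since neither transcription nor message stability was measured.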

How the results depend on the processing

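The times without transcripts of the other tissue in fed libraries, the term for fed times with such transcripts, the intronic values per exonic read, the length settings, the genes left out and the separate fits were chosen after seeing the data. Counts of changed or rhythmic genes stayed within 1.5 times the reported value under pseudocounts of 0.1 and 1, median-of-ratios scaling, quantile normalisation, robust empirical Bayes, no time covariate, the 6-level time factor for rhythms and the replicate block. Without a filter, more genes were tested, and 5503 genes in liver and 7533 in muscle passed for exonic minus intronic, and 11105 for the tissue difference. With intronic values per exonic read, 5095 passed for exonic minus intronic in liver, as the setting shifts every gene of a library. With the term for fed times that held transcripts of the other tissue, 1741 genes were rhythmic in fed liver, 1398 differed in liver and 267 were rhythmic in fed muscle; the term overlaps with time of day. At ZT16 and ZT20 alone, with fewer libraries, 4154 genes changed in intronic signal and 2071 in exonic minus intronic. With a preset correlation 12 lists passed in liver and 11 in muscle, and with median-of-ratios scaling 4 in liver; the cause was not tested.

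Gene by gene, alternatives are given for the genes the text names, a set narrowed after seeing the data from the 501 effects of all genes given by the rule. Over that wider set directions turned for 17 effects at the 2 times whose fed libraries lacked transcripts of the other tissue, 10 at ZT0 alone in liver (5 with the length trend removed), 17 with intronic values per exonic read, 4 with a pseudocount of 0.1, 2 with quantile normalisation and 1 with median-of-ratios scaling, and for 0 with one library left out; the cause was not tested. Among the named genes, Cyp8b1 in muscle (0.25) and Mybpc2 exonic minus intronic in liver (0.27) turned in direction at the 2 times whose fed libraries lacked transcripts of the other tissue, where 9 other calls were lost; the cause was not tested. Fasted liver of ZT4 held muscle transcripts, and at ZT0 alone, also chosen after seeing the data, Mybpc2 did not turn (-0.17) but did not pass. Calls of other named genes ended at ZT0 alone with the length trend removed (Tnnt1 in liver), with quantile normalisation (Tnnt1 in liver, Alas2 in muscle), without a filter (rhythms of Clock and Wee1 in fasted liver), without the libraries of steep length slope (these 2 and Ciart), with a pseudocount of 0.1 (Hsd3b5 exonic minus intronic in liver) and, for 9 fed rhythms, with the term for fed times. Calls were gained by S100a8 in muscle (pseudocount 0.1, both other scalings, the replicate block, no time covariate and both length settings), Nr3c1 in muscle (both length settings), Dcn and Myh1 in muscle (median-of-ratios scaling), Tnnt3 exonic minus intronic in muscle (quantile normalisation), Hadh in liver (ZT0 and ZT4, and ZT0 alone with and without the length trend), and by rhythms of Rora in fasted liver (pseudocount 1 and separate fits), Pfdn1 in fed liver and Per1 in fasted muscle (separate fits). Of the values with one library left out, 8 lost and 23 gained a call and 9797 did neither, the lost calls being those of Wee1 and Clock in fasted liver and the gained ones those of Hadh in liver, Nr3c1 and S100a8 in muscle, and the rhythms of Rora and Nampt in fasted liver and Dbp in fasted muscle. Counts with one library left out ranged over 7717 to 8071 for fasting in liver and 9118 to 9282 in muscle, 6550 to 6732 for the tissue difference, 3531 to 4887, 2789 to 4061 and 2844 to 3901 for fed, fasted and differing rhythms in liver, 405 to 585, 4972 to 5866 and 3360 to 4186 in muscle, 5099 to 5345 and 6257 to 6410 for intronic signal in liver and muscle, and 2858 to 3318 and 4262 to 4432 for exonic minus intronic.

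Replicate numbers showed little pairing of samples: deviations of same-numbered libraries correlated with a mean r of 0.0571 between fed and fasted liver (lowest -0.118), 0.0605 in muscle and 0.0621 between tissues. These rest on 11, 12 and 19 pairs. They do not show whether same-numbered liver and muscle came from 1 mouse, and the labels do not say. With the replicate block, 7690 genes changed in liver, 9114 in muscle and 6658 differed between tissues. At the estimated depth, genes near 1 FPKM on short transcripts rest on few reads.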

Other observations

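The comparison of intron share was chosen after the data were seen, and the gene lists were set before.

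Of 17 somatotropic and male-biased genes in liver, 1 rose, 11 fell and 5 did not pass (adjusted p = 0.765 with an estimated correlation), including the growth hormone receptor gene Ghr (-1.38 ± 0.12) and the IGF carrier subunit gene Igfals (-1.90 ± 0.17), while Igfbp2 (1.27 ± 0.12) rose; with median-of-ratios scaling 7 fell and 2 rose. In muscle, 1 rose, 9 fell and 1 did not pass of 11 (adjusted p = 0.196 with an estimated correlation), including Igf1 (-1.95 ± 0.10), Ghr (-1.06 ± 0.075) and Bcl6 (-1.82 ± 0.14). Of 18 xenobiotic metabolism genes in liver, 6 rose, 8 fell and 4 did not pass, against 7 and 7 with median-of-ratios scaling (adjusted p = 0.961 with an estimated correlation); the falls included Cyp1a2 (-2.64 ± 0.14) and Ces2a (-1.14 ± 0.076) and Cyp2c29 and Gstm1, whose reads can be shared with paralogs (-2.22 ± 0.11 and -1.58 ± 0.098). In muscle, 1 rose, 1 fell and 2 did not pass on the deposited scale, against 2 rises and 0 falls with median-of-ratios scaling (adjusted p = 0.92 with an estimated correlation). Of the muscle cell cycle genes, 2 rose, 4 fell and 0 did not pass, against 3 rises and 2 falls with quantile normalisation and 2 and 2 at ZT16 and ZT20 alone (adjusted p = 0.946 with an estimated correlation), with Ccnd1 (-1.90 ± 0.091) falling and the ribonucleotide reductase gene Rrm2 (1.27 ± 0.073) rising. None of 8 nerve and Schwann cell markers passed in muscle by limma, with 2 at an unadjusted p under 0.05 and 2 rises with median-of-ratios scaling (adjusted p = 0.92 with an estimated correlation). In muscle the cholangiocyte marker Spp1 (0.13 ± 0.29) and the neutrophil marker S100a8 (0.34 ± 0.16) did not pass over all genes, the erythroid marker Alas2 (-0.46 ± 0.080) fell but did not pass with quantile normalisation, and 0 pancreas markers passed the filter. S100a8 (adjusted p = 0.0522) passed when 1 library was left out, which was fasted ZT0 replicate 3 (0.0382), fasted ZT4 replicate 2 (0.0321), fasted ZT4 replicate 5 (0.0452), fasted ZT8 replicate 3 (0.0353), fasted ZT12 replicate 2 (0.0391), fasted ZT12 replicate 3 (0.0391), fasted ZT16 replicate 1 (0.0497), fasted ZT20 replicate 1 (0.0467), fed ZT0 replicate 5 (0.043), fed ZT4 replicate 1 (0.0363), fed ZT4 replicate 5 (0.028), fed ZT16 replicate 4 (0.0415) or fed ZT20 replicate 1 (0.0364), with the adjusted p in parentheses.

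The intronic share of reads was on average higher in fasted libraries. The estimated ratio of intronic to exonic depth was 1.56-fold higher in fasted than in fed liver, at 5 of 6 times (permutation test, two-sided p = 2.50e-04), and 1.11-fold higher in fasted muscle, at 5 of 6 times (p = 0.0308). In liver the fold varied over the times from 0.947 to 4.35, the highest at ZT0, so the mean does not stand for every time. In muscle it ran from 0.969 to 1.26. At ZT0 the relative ratio was 0.422 ± 0.0861 (SD, n = 3) in fed and 1.81 ± 0.108 in fasted liver, and at ZT12 1.26 ± 0.17 and 1.21 ± 0.283. The slope of the level on transcript length differed too. It was higher in every fasted than in every fed library at ZT0, ZT8, ZT16 and ZT20 in liver and at ZT0, ZT12 and ZT16 in muscle, but not at the other times. The 3 muscle libraries of lowest ratio, fed ZT16 replicate 5 (0.63, slope -0.261), fed ZT4 replicate 1 (0.747, slope -0.183) and fasted ZT4 replicate 2 (0.777, slope -0.10), were among those of steep slope.

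Gapdh, the glycolytic enzyme gene with many processed copies, stood at 32.4 ± 3.84 FPKM (SD, n = 12) in fed muscle of ZT0 to ZT12 and at 11.4 ± 0.79 FPKM (n = 6) at ZT16 and ZT20. In fasted muscle it stood at 9.99 ± 4.35 FPKM (n = 12) and 9.56 ± 1.70 FPKM (n = 6) at the same times. The high level thus fell on the fed libraries that held liver transcripts. At ZT0 to ZT12, feeding state in muscle cannot be told apart from whatever else set these libraries apart. In the fed liver library of ZT20 numbered replicate 4, the acute-phase gene Saa1 stood at 9545 FPKM.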
